A study of Homo sapiens with 24 samples.

How the data were processed

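RNA from acute myeloid leukaemia (AML) bone marrow cells, thawed and sorted into fractions that the labels call leukaemia stem cells, was sequenced as 24 libraries from 6 donors. Per the labels' protocols, 200 ng of total RNA was taken into a stranded, poly(A)-selected library preparation and read as 100 nt single-end reads. There were 9 libraries from diagnosis and 15 from relapse. The sort gates in the labels are a first marker (34 in 16 libraries, 32 in 8), negative or positive, and then CD38, negative or positive. Here 34 was read as CD34 and 32 as CD32. The labels do not state which drugs each donor received.

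The deposited table holds 1 column per library and 21845 genes by symbol. Its values are a normalised signal: read counts per gene that the authors divided by 1 size factor per library and rounded to 2 decimals. That reading comes from the values, since every value below 1000 reads was a whole multiple of its library's step (100% of values, within a rounding tolerance of 0.0051). A single read was worth between 0.583 and 4.44 normalised counts. Whole reads were recovered from these steps and gave 18.1 to 33.6 M reads per library. Depth is not enough for genes near 0 reads in some donors. Among the named genes, PPARGC1A, HIST3H2A, VAT1L and CD34 (relapse) and CD3D, ELANE and MS4A3 (CD38) had a normalised count of 0 in 1 or 2 donor values. The submitters' processing notes name bcl2fastq 2.19.0, Trimmomatic 0.36, STAR 2.6.0c, Subread 1.6.1 with featureCounts, DESeq2 1.16.1 and R 3.4.1, and the builds GRCh38 and hg38. The annotation, the strand setting and the row filter are not given in the sources used here. Every deposited row had values above 0 in at least 10 libraries and a row mean of at least 2.148, so genes silent in most libraries are not in the table. Size factors recomputed from the deposited values lay between 0.982 and 1.07.

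Y-linked genes and XIST were left out because the donors are patients, which left 21823 genes. Coordinates are from GENCODE 29 on GRCh38, in which 16690 of the table's symbols matched 1 gene. Reads of near-identical copies (FCGR2A and FCGR2B, the HLA class II genes, HBG2) cannot be assigned with certainty. Antisense genes such as KLF3-AS1 are uncertain too, because the strand setting of the counting is not stated.

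The donor was the replicate. For relapse against diagnosis, the 18 libraries whose donor and gate were sorted at both stages were averaged per donor and stage, giving 6 values against 6. For CD38-negative against CD38-positive cells, the 18 libraries that form 9 pairs of the same donor, stage and first gate were averaged per donor and CD38 gate, giving 5 values against 5. The interaction of stage and CD38 gate used the 12 libraries of the 3 donors with both gates at both stages. The donor was kept as a block, or donor by stage in the interaction. The pairing comes from the donor in the labels. Deviations from the stage means correlated across genes at 0.674 to 0.908 within donors and at -0.589 to 0.300 between donors.

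The design fixed before the data were examined assumed raw counts and named edgeR. The deposited unit is not raw counts, so the main test was limma 3.58.1 (R 4.3.3) on log2(normalised count + 2), with a mean-variance trend. Fold changes are on that scale, which understates the change of low genes. Genes needed at least 10 normalised counts in at least 6 values (relapse), 5 values (CD38) or 3 libraries (interaction). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. edgeR 4.0.16 on the recovered reads was run as an alternative, as was DESeq2 1.42.0. Each p-value in the text is from limma unless another tool is named. An SE is that of limma's fit, and an SD is over donors.

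Before the data were examined, 35 gene lists with 714 entries were fixed. Of these, 676 entries were found in the table, 18 of them under another symbol. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. That left 34 lists, because the neutrophil list had too few members past the filter. Single members were also adjusted over their list alone, separately in each list. These calls are not adjusted for the number of lists, so they do not hold the threshold over all lists or all genes. The named genes followed a rule also fixed in advance. It took the genes past the threshold with the same direction in every donor, up to 8 each way. Where fewer than 3 qualified it took the 5 of smallest p in that direction, which are given without being called changed. It added a fixed set of sort markers, fatty acid genes and BCL2 family genes, and the 3 members of smallest p of each list past the set test.

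The tests were checked on simulated counts with real gene means, library sizes and dispersions and 200 changed genes, besides monocyte markers set 2-fold lower. Simulated genes varied independently, and each change was the same in every donor. In the relapse design (16526 genes), limma recovered 56.0% of 2-fold, 93.9% of 4-fold and 98.0% of 8-fold changes, with 5 false calls. In the CD38 design (16842 genes) it recovered 38.0%, 84.0% and 96.0%, with 4 false calls. DESeq2 made 57 and 71 false calls in the same simulations. The recovered shares need not hold for the real data, in which donors differ and genes move together. There S100A8 was 8.73-fold lower at relapse and did not pass (adjusted p = 0.256). No pair of libraries agreed within sampling noise, the lowest median chi-square ratio over 276 pairs being 7.549. Alternatives covered the block, the scaling, the tool, the filter on low values, the pseudocount, the pooling of libraries, each donor left out, and marker means as covariates. Figures were drawn with matplotlib.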

Results

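The series asks how AML stem cell fractions differ between diagnosis and relapse, in a study of fatty acid metabolism and resistance to venetoclax, an inhibitor of the anti-apoptotic protein BCL2. Transcriptomes were measured in 24 libraries of sorted marrow cells from 6 donors, 9 from diagnosis and 15 from relapse. Depth was 27.4 ± 5.45 M reads per diagnosis library (SD, n = 9) and 25.7 ± 4.23 M per relapse library (SD, n = 15). The sort labels were checked against the transcripts of the sorted proteins. The CD38 transcript was higher in the CD38-positive library of 9 of 9 pairs, and CD34 was higher in the CD34-positive library of 2 of 2 pairs. Across donors, 8 of 9 CD34-positive libraries had more CD34 transcript than every CD34-negative library, and 1 did not match its label. That library is the only diagnosis library of its donor, so every relapse change of that donor rests on it. With limma no single gene passed the adjusted threshold over all genes in any comparison, so the log2 changes of single genes are estimates.

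At relapse, monocyte markers were on average lower in the matched fractions of every donor. The mean log2 change of 22 monocyte markers was -1.18 ± 0.69 (SD, n = 6 donors), and 21 of the 22 were lower. Granulocyte and monocyte progenitor markers changed by -1.05 ± 0.96 and were lower in 5 of 6 donors. Camera placed both lists below other genes (adjusted p = 3.5e-11 and 1.6e-08). With an estimated correlation the adjusted p was 0.380 and 0.510, so these calls rest on the preset correlation.

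Over all 16563 genes, no monocyte marker passed the threshold, whereas 7 fell when adjusted over the list alone, a looser adjustment that does not count the other lists. S100A8 and S100A9, which form the calcium-binding protein calprotectin, changed by -3.13 ± 0.44 and -2.83 ± 0.45 log2 units (SE). S100A8 averaged 10027 normalised counts at diagnosis and 1057 at relapse. FCN1, a secreted lectin of monocytes, changed by -2.47 ± 0.39, and CD14, the lipopolysaccharide co-receptor, by -2.02 ± 0.37. Some donors hardly expressed these genes at either stage. In log2(normalised count + 2), S100A8 went from 6.50 to 2.40 in the donor of the mismatched CD34 library and from 6.90 to 5.31 in another. In the others it was at least 13.0 at diagnosis. CD14 went from 3.66 to 2.67 and from 3.89 to 2.80 in the same low donors. Among 15 progenitor markers, 9 fell when adjusted over the list alone. ELANE, which encodes neutrophil elastase, changed by -1.97 ± 0.35, RNASE2, an eosinophil granule ribonuclease, by -1.70 ± 0.23 and LYZ, lysozyme, by -2.14 ± 0.42. ELANE and RNASE2 were lower in 6 of 6 donors and LYZ in 5 of 6.

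Stem cell lists were higher on average. The genes of the LSC17 stemness score changed by 0.69 ± 0.87 (SD, n = 6) and were higher in 5 donors, and 16 of 17 members were higher (camera adjusted p = 8.7e-06, and 0.510 with an estimated correlation). DNMT3B, a DNA methyltransferase, changed by 1.10 ± 0.25 (SE) and NYNRIN by 0.70 ± 0.15, and these 2 members rose when adjusted over the list alone. Stem and progenitor markers changed by 0.53 ± 0.58 (SD, camera adjusted p = 0.0168, and 0.510 with an estimated correlation), among them the transcription factor GATA2 at 1.70 ± 0.51 (SE). CD34 itself changed by 1.86 ± 0.66. It was 1.08 without 1 donor, whose value involves the library that did not match its CD34 label, and the other 5 donors were higher. Some of these 5 hardly expressed CD34. In log2(normalised count + 2), it went from no reads to 2.94, from 1.67 to 3.48 and from 4.56 to 5.16. In the donors with the most CD34 it went from 10.68 to 11.47 and from 12.56 to 12.83. In donors sorted on CD34 first, its level is also a product of the sort. With each donor left out, the mean was 0.42 to 0.89 for LSC17, 0.35 to 0.65 for the stem list and 0.03 to 0.61 for the erythroid list. The stem list passed in 4 of 6 fits that each left out 1 donor (highest adjusted p = 0.0676). Erythroid markers moved in the same direction, by 0.46 ± 1.09 (SD), and were higher in only 3 donors (camera adjusted p = 0.0192, and 0.761 with an estimated correlation). Without 1 donor camera placed the erythroid list below other genes (adjusted p = 0.992), and with the monocyte marker mean as a covariate it placed the LSC17 and stem lists below them (adjusted p = 0.620 and 0.722). None of these turned directions passed. The covariate was itself lower at relapse in 6 of 6 donors, so it overlaps with stage.

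**Figure D1:**
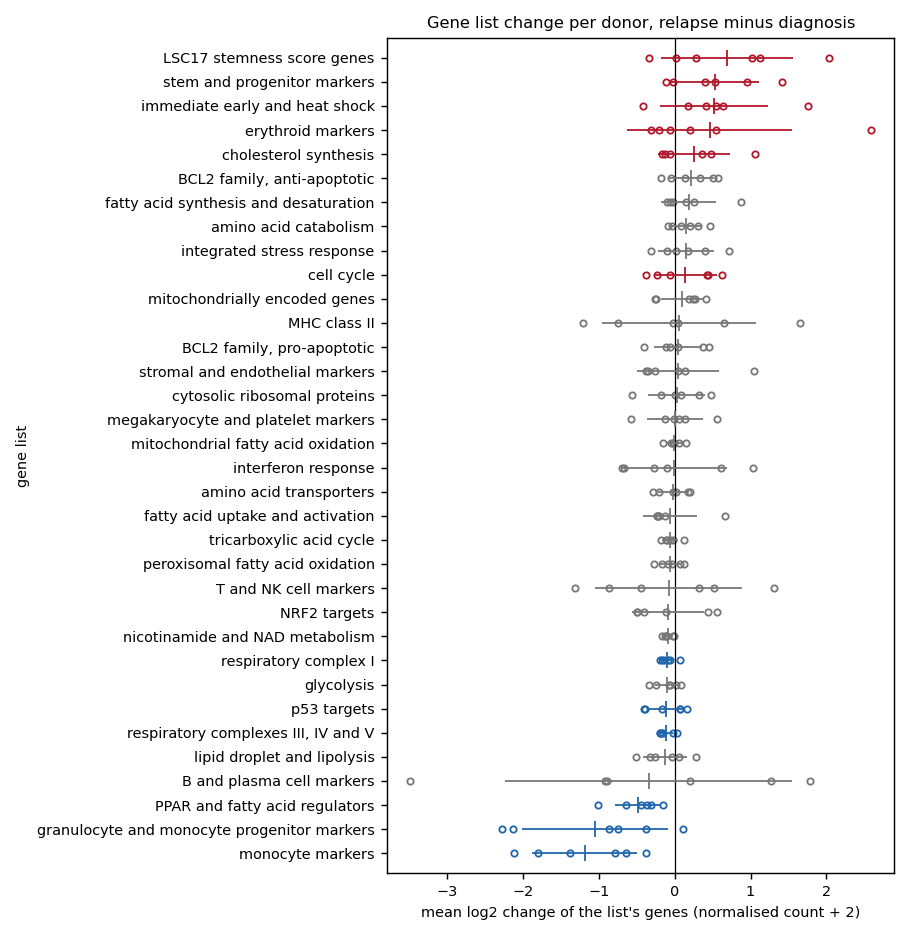
Mean log2 change of each gene list from diagnosis to relapse on the horizontal axis, with 1 open circle per donor (n = 6), a tick at the mean and a bar of 1 SD. Red lists were higher and blue lists lower by camera with the preset correlation, and grey lists did not pass. Monocyte markers lie below 0 in all 6 donors, at a mean of -1.18, while mitochondrial fatty acid oxidation lies at -0.01.

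The lists of fatty acid oxidation and of fatty acid uptake did not pass. The 21 measured genes of mitochondrial fatty acid oxidation changed by -0.01 ± 0.10 (SD, n = 6, camera adjusted p = 0.785), and the 17 of fatty acid uptake and activation by -0.06 ± 0.35 (adjusted p = 0.648). The uptake list was lower in 5 of 6 donors, by 0.13 to 0.23, and 1 donor went the other way (0.66). The diagnosis value of that donor is the library that did not match its CD34 label. With each donor left out, the mean of the uptake list was -0.20 to -0.02, and that of the oxidation list -0.04 to 0.02. CPT1A, the carnitine acyltransferase that admits long-chain fatty acids to mitochondria, changed by 0.18 ± 0.13 (SE), CPT2 by -0.01 ± 0.15 and the dehydrogenase ACADVL by 0.03 ± 0.10. CD36, a fatty acid translocase, changed by -0.38 ± 0.82 and was lower in 4 of 6 donors. Its largest rise was in the donor of the mismatched CD34 library, without whom the mean was -1.34. With each donor left out, the mean was -1.34 to 0.07 for CD36, 0.06 to 0.25 for CPT1A, -0.08 to 0.11 for CPT2 and -0.03 to 0.11 for ACADVL. ACSL1, which activates long-chain fatty acids, changed by -0.74 ± 0.18, was lower in 6 of 6 donors and fell when adjusted over its list alone. PPAR and other fatty acid regulators changed by -0.49 ± 0.31 (SD) and were lower in 6 donors (camera adjusted p = 0.00561, and 0.380 with an estimated correlation). PPARGC1A, a coactivator of mitochondrial biogenesis, changed by -3.10 ± 0.48 (SE), from a mean of 222 normalised counts to 18.1, and was the member of that list that fell when adjusted over it alone. In log2(normalised count + 2), its diagnosis value was 9.81 in 1 donor, 8.34 in another and 6.19 or less in the others. At relapse it lay at or near 0 counts in most donors, so its size of change is uncertain. With the monocyte marker mean, which overlaps with stage, as a covariate the list of PPAR and fatty acid regulators turned upward but did not pass (adjusted p = 0.782).

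Nuclear-encoded genes of oxidative phosphorylation were lower by small amounts. Respiratory complexes III, IV and V changed by -0.12 ± 0.10 (SD) with 32 of 35 members lower, and complex I by -0.10 ± 0.09 with 33 of 38 lower. Camera adjusted p was 1.3e-06 and 3.1e-05, and 0.510 for each with an estimated correlation. The 13 mitochondrially encoded genes went the other way, by 0.10 ± 0.28 (SD). Of these 11 were higher, and the list did not pass (camera adjusted p = 0.107). Cholesterol synthesis genes changed by 0.26 ± 0.48 and were higher in 3 of 6 donors, immediate early and heat shock genes by 0.52 ± 0.71 in 5 donors, and cell cycle genes by 0.14 ± 0.41 in 3 donors. Camera adjusted p was 0.000140, 4.2e-05 and 0.0103, and 0.656, 0.563 and 0.785 with an estimated correlation. In the 6 fits that each left out 1 donor, these lists passed in 5, 5 and 3 (highest adjusted p = 0.0572, 0.0631 and 0.637), with means of 0.10 to 0.34, 0.27 to 0.71 and 0.04 to 0.24. Within these lists the log2 change was 0.75 ± 0.23 (SE) for SQLE, a sterol synthesis enzyme, and 1.24 ± 0.29 for the immediate early factor NR4A1, neither past the threshold. Targets of p53 changed by -0.11 ± 0.25 (SD, camera adjusted p = 0.0192, 0.510 with an estimated correlation, and past the threshold in 4 of 6 fits without 1 donor, with means of -0.16 to -0.05), and the death receptor FAS, 1 of them, by -0.77 ± 0.14 (SE). With the monocyte covariate the cell cycle and p53 lists turned direction (adjusted p = 0.121 and 0.344), and cell cycle genes also did with all 24 libraries (adjusted p = 0.243).

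In the BCL2 family, BCL2 changed by 0.36 ± 0.22, MCL1 by 0.20 ± 0.16, BCL2L1 by 0.08 ± 0.14, BCL2A1 by -0.31 ± 0.37 and BAX by -0.24 ± 0.13 (SE). With each donor left out, these means were 0.19 to 0.52, 0.12 to 0.35, -0.03 to 0.14, -0.54 to 0.01 and -0.32 to -0.14. The anti-apoptotic list did not pass (camera adjusted p = 0.169). BCL2L10, chosen after its value was seen, rose by 0.99 ± 0.29 when adjusted over that list alone. NAMPT, the rate-limiting enzyme of NAD salvage, changed by -0.55 ± 0.22. The remaining lists did not pass, 22 of 34 in all.

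**Figure D2:**
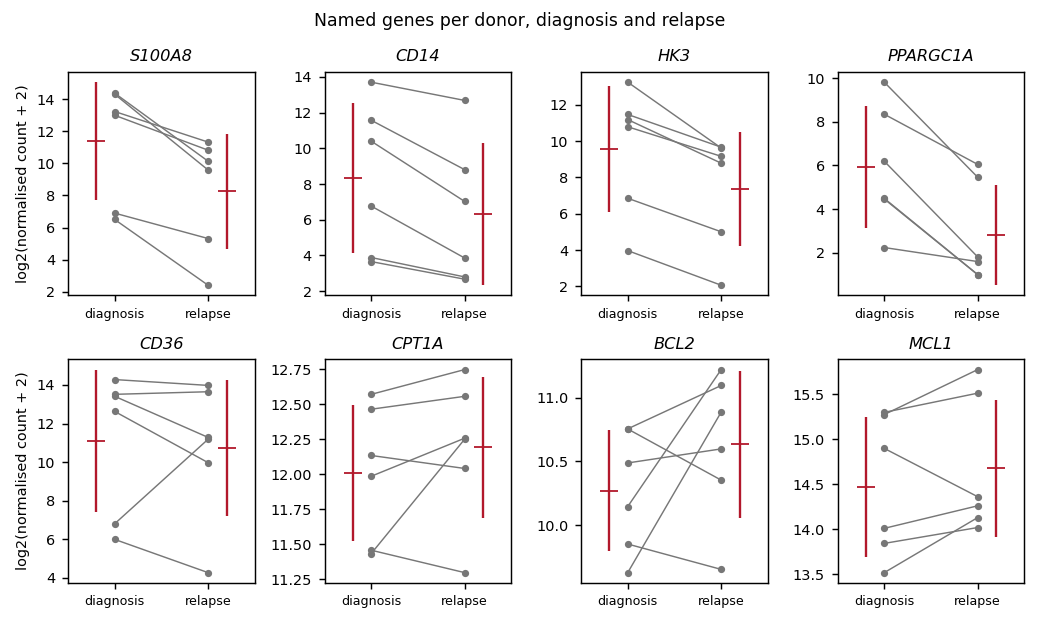
Normalised counts of 8 named genes at diagnosis and relapse, as log2(normalised count + 2) on the vertical axes, whose ranges differ between panels. Grey lines join the values of 1 donor (n = 6), and red marks are the mean and 1 SD. S100A8, CD14, HK3 and PPARGC1A are lower at relapse in 6 of 6 donors, whereas CD36, CPT1A, BCL2 and MCL1 go both ways.

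Among the genes with the smallest p-values, HK3, SLC36A4, RNASE2 and S100A8 were lower at relapse. HK3 (chromosome 5, 176880869 to 176899332), a hexokinase of myeloid cells, was 4.59-fold lower (log2 change -2.20 ± 0.25 SE, p = 1.9e-05). SLC36A4 (chromosome 11, 93144171 to 93197964), an amino acid transporter, changed by -0.72 ± 0.09 (p = 3.6e-05). RNASE2 and S100A8 had p-values of 6.8e-05 and 9.2e-05. Among those higher were KLF3-AS1 at 1.48 ± 0.20 (p = 5.6e-05), SFMBT2 at 0.85 ± 0.14 (p = 0.000303), VAT1L at 2.12 ± 0.37 (p = 0.000388), the linker histone gene H1F0 at 0.90 ± 0.16 (p = 0.000411) and the histone gene HIST3H2A at 1.09 ± 0.19 (p = 0.000442). All 9 went the same way in 6 of 6 donors.

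No gene passed the adjusted threshold between relapse and diagnosis with limma (lowest adjusted p = 0.256) or edgeR. At an unadjusted p under 0.05 there were 1380 genes (618 higher, 762 lower), against 828 expected by chance, and DESeq2 called 243 genes (76 higher, 167 lower). The fit with no donor block also called 0.

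CD38-negative and CD38-positive fractions of the same specimens were compared in 5 donors. By camera with the preset correlation, CD38-negative cells had lower transcripts for cell division and for granule proteins of myeloid progenitors than CD38-positive cells. Nuclear-encoded transcripts for mitochondrial respiration were also lower in CD38-negative cells. They had higher transcripts of stem cell, interferon and MHC class II genes. None of the 16 list calls held with an estimated correlation (lowest adjusted p = 0.555). Markers of T, NK, B and erythroid cells were higher as well, in 3 to 4 of the 5 donors. The CD38 transcript, a product of the sort, changed by -2.93 ± 0.43 (SE).

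Cell cycle genes changed by -1.68 ± 1.11 (SD, n = 5 donors), with 30 of 30 members lower, and 29 of them fell when adjusted over the list alone (camera adjusted p = 2.5e-19). PCNA, the DNA polymerase clamp, changed by -1.16 ± 0.21 (SE), the mitotic kinesin KIF11 by -1.48 ± 0.24 and the spindle factor TPX2 by -1.63 ± 0.30. Granulocyte and monocyte progenitor markers changed by -2.75 ± 1.37 (SD) with 15 of 15 lower, 10 of them past the threshold over the list alone (camera adjusted p = 7.8e-11). The serine protease PRTN3 changed by -5.38 ± 0.86 (SE), ELANE by -3.70 ± 0.61 and MS4A3 by -3.44 ± 0.31. With an estimated correlation the adjusted p of both lists was 0.555. In the same libraries T and NK cell markers were higher by 1.44 ± 1.43 (SD) and erythroid markers by 2.41 ± 3.22.

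Respiratory complexes III, IV and V changed by -0.38 ± 0.20 (SD), complex I by -0.25 ± 0.14 and the tricarboxylic acid cycle by -0.21 ± 0.14, each lower in 5 of 5 donors. Over the list alone, 29 of 35, 3 of 38 and 8 of 23 members fell. Examples were CYC1 of complex III at -0.58 ± 0.12 (SE), NDUFB9 of complex I at -0.61 ± 0.12 and the succinate dehydrogenase subunit SDHB at -0.40 ± 0.09. Cytosolic ribosomal protein genes changed by -0.44 ± 0.36 (SD) with 43 of 43 lower. Mitochondrial fatty acid oxidation changed by -0.16 ± 0.16 and was lower in 4 of 5 donors, with ECHS1, an enoyl-CoA hydratase, at -0.50 ± 0.11 (SE). Fatty acid synthesis and desaturation changed by -0.21 ± 0.12 (SD), with FASN, the fatty acid synthase, at -0.86 ± 0.19 (SE). Amino acid catabolism changed by -0.46 ± 0.30 (SD), with the alanine transaminase GPT2 at -1.32 ± 0.20 (SE). Camera adjusted p for these 7 lists lay between 2.6e-16 and 0.00503, and with an estimated correlation between 0.555 and 0.630. The 13 mitochondrially encoded genes were not lower. Their list changed by 0.19 ± 0.48 (SD), was higher in 2 of 5 donors and did not pass (camera adjusted p = 0.244).

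**Figure D3:**
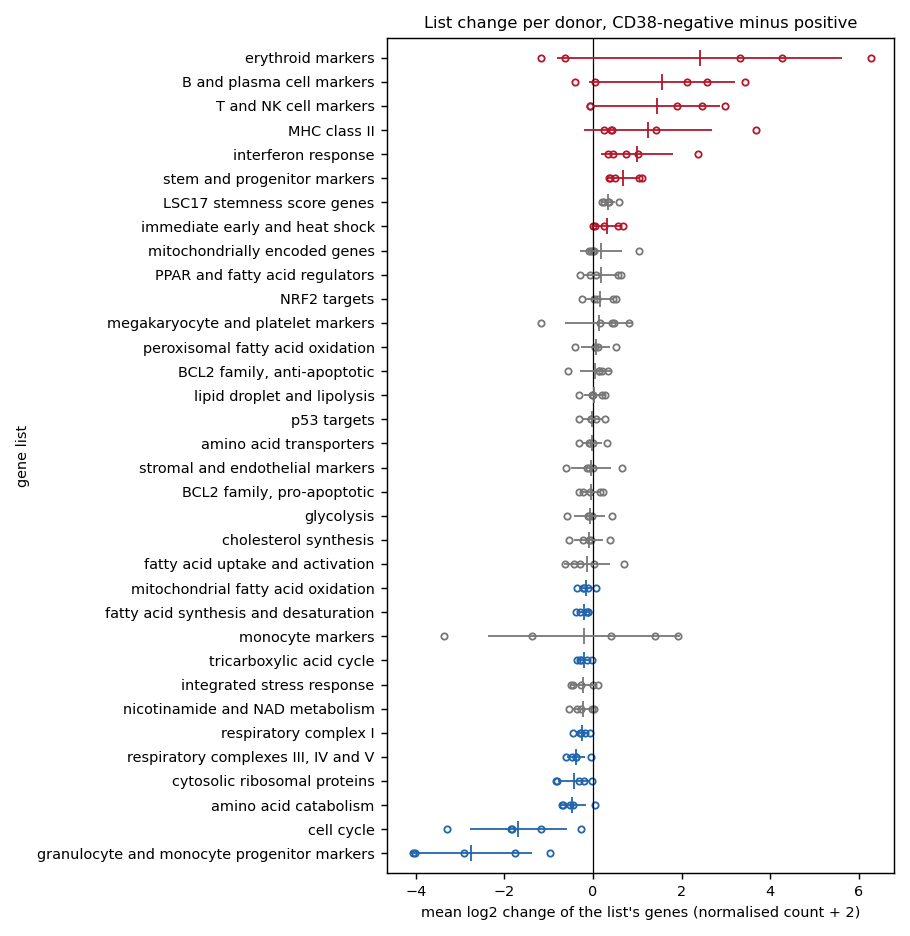
Mean log2 change of each gene list between CD38-negative and CD38-positive cells on the horizontal axis, with 1 open circle per donor (n = 5), a tick at the mean and a bar of 1 SD. Red lists were higher and blue lists lower by camera with the preset correlation, and grey lists did not pass. Cell cycle genes lie below 0 in all 5 donors, and erythroid markers range widely around a mean of 2.41.

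Stem and progenitor markers were higher in CD38-negative cells of 5 of 5 donors, by 0.68 ± 0.37 (SD, camera adjusted p = 0.00178, and 0.555 with an estimated correlation). HLF, a transcription factor of haematopoietic stem cells, changed by 1.56 ± 0.32 (SE), CD34 by 1.58 ± 0.35 and SPINK2 by 0.70 ± 0.14. Interferon response genes changed by 0.99 ± 0.82 (SD) with 21 of 22 higher, 12 of which rose when adjusted over the list alone, and IFIT2 changed by 1.49 ± 0.32 (SE). MHC class II genes changed by 1.24 ± 1.44 (SD), with HLA-DQB1 at 1.17 ± 0.30 (SE), and immediate early and heat shock genes by 0.31 ± 0.30 (SD). Camera adjusted p for the last 3 lists was 7.3e-06, 0.00136 and 0.0142, and 0.630 for each with an estimated correlation. The immediate early list passed in 4 of 5 fits that each left out 1 donor (highest adjusted p = 0.0525). With each donor left out, the mean was 0.64 to 1.15 for interferon genes and 0.63 to 1.48 for MHC class II genes.

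Lymphoid and erythroid markers varied widely between donors. The T and NK cell list was higher in 3 of 5 donors, the B and plasma cell list, which changed by 1.56 ± 1.66 (SD), in 4 and the erythroid list in 3. Their camera adjusted p was 0.000365, 0.0356 and 0.0178, and 0.630, 0.687 and 0.725 with an estimated correlation. The B and plasma cell and the erythroid list each passed in only 2 of the 5 fits that left out 1 donor (highest adjusted p = 0.364 and 0.297), and the mean of the latter was 1.45 to 3.31. LCK, a T cell kinase, changed by 2.54 ± 0.52 (SE), CD22, a B cell receptor inhibitor, by 3.28 ± 0.65 and SLC4A1, the red cell anion exchanger, by 4.62 ± 1.36. Monocyte markers changed by -0.21 ± 2.17 (SD) and did not pass (camera adjusted p = 0.645). CD36, which erythroid precursors also express, changed by 1.29 ± 0.91 (SE), CPT1A by -0.12 ± 0.10 and BCL2 by -0.29 ± 0.28. With each donor left out, these means were 0.31 to 2.13, -0.17 to -0.05 and -0.64 to -0.14, and that of monocyte markers -0.74 to 0.58. The 18 other lists did not pass.

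**Figure D4:**
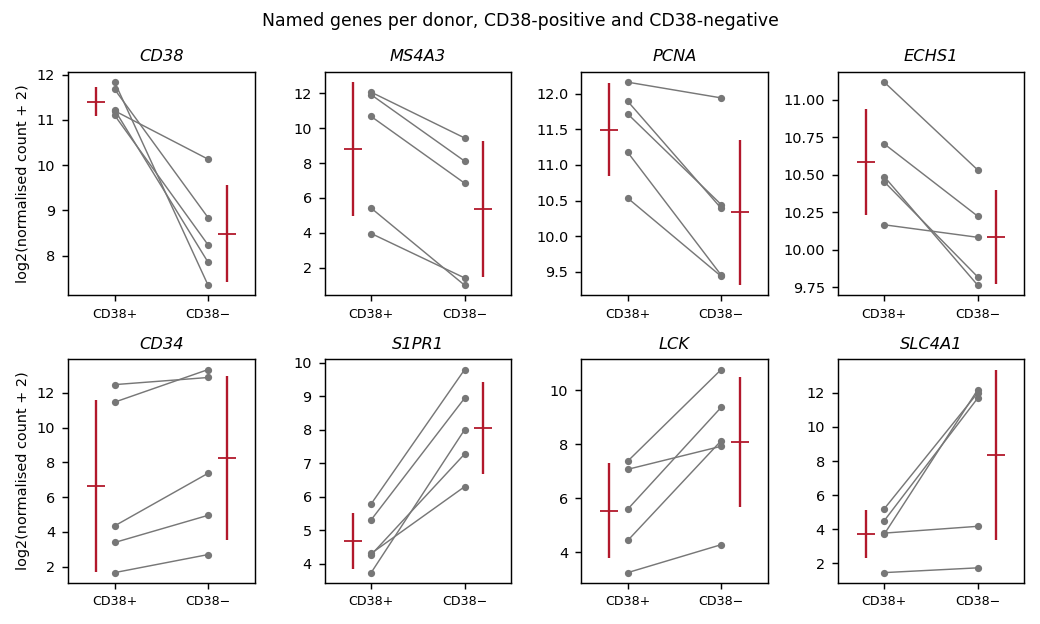
Normalised counts of 8 named genes in CD38-positive and CD38-negative cells, as log2(normalised count + 2) on the vertical axes, whose ranges differ between panels. Grey lines join the values of 1 donor (n = 5), and red marks are the mean and 1 SD. CD38, MS4A3, PCNA and ECHS1 are lower, and CD34, S1PR1, LCK and SLC4A1 higher, in the CD38-negative cells of 5 of 5 donors.

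The smallest p-values among genes higher in CD38-negative cells belonged to CYTIP, S1PR1, TNFSF8, C10orf128 and PTPRM. CYTIP (chromosome 2, 157414619 to 157488961), a regulator of leukocyte adhesion, was 2.39-fold higher (log2 change 1.26 ± 0.11 SE, p = 8.7e-06). S1PR1, the sphingosine-1-phosphate receptor, changed by 3.38 ± 0.34 (p = 2.6e-05), TNFSF8, the CD30 ligand, by 2.42 ± 0.26 (p = 4.1e-05), C10orf128 by 2.13 ± 0.23 (p = 4.1e-05) and PTPRM by 1.93 ± 0.23 (p = 7.3e-05). Among those lower were MS4A3 (p = 1.2e-05), COCH at -1.28 ± 0.12 (p = 1.7e-05), NCR3LG1 at -1.28 ± 0.16 (p = 9.6e-05), the nucleotide receptor P2RY2 at -1.84 ± 0.23 (p = 0.000116) and the histone gene HIST1H2BO at -1.39 ± 0.18 (p = 0.000137). All 10 went the same way in 5 of 5 donors.

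No gene passed the adjusted threshold with limma (lowest adjusted p = 0.0850) or edgeR, out of 16861 tested. There were 4521 genes at an unadjusted p under 0.05 (2518 higher, 2003 lower) against 843 expected by chance, and 24.6% of genes went the same way in all 5 donors against 6.25% by chance. Without 1 of the donors limma called 1174 genes (511 higher, 663 lower), DESeq2 called 2050 in all 5 donors, limma-voom called 4, and the 9 pairs taken as separate blocks gave 3677. The fit with no donor block called 0.

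Whether the CD38 difference changed between diagnosis and relapse was tested in 3 donors. No gene of 18704 passed with limma, edgeR or DESeq2, and 241 had an unadjusted p under 0.05, against 935 expected by chance. The fit did not let the CD38 difference vary by donor, so diagnosis and relapse of a donor were not paired in this contrast. Donor variation in the CD38 difference therefore counted as error. The median SE of this contrast was 0.418 log2 units, against 0.180 for relapse and 0.178 for the CD38 gate, so only large differences were detectable.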

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

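The tests of library scaling, of the mature monocyte share and of dilution were chosen after the results they bear on had been seen, as were the split counts for genes past the adjusted threshold. The remaining split counts and the test of single donors behind the DESeq2 calls were set before their results were seen, but the rule for reading the latter was made stricter afterwards.

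Across 206 sets of values, 12 had 1 value far from the rest, against 10.3 expected by chance. From diagnosis to relapse, 1 donor stood apart for each of CD34 (5.78 log2 units, others 0.27 to 1.94), NPR3 (4.26, others 0.60 to 1.20) and GATA1 (2.15, others 0.14 to 0.55). It was a different donor for each gene. The CD34 value involves the 1 of 9 CD34-positive libraries whose CD34 transcript did not match its label, so it is not read as a rise. For whole lists, 1 donor stood apart for each of erythroid markers (2.59, others -0.31 to 0.54), stromal and endothelial markers (1.05, others -0.37 to 0.14) and fatty acid uptake and activation (0.66, others -0.23 to -0.13). The erythroid value came from the donor that stood apart for GATA1. The stromal and the uptake values came from the donor that stood apart for CD34, and so involve the same mismatched library. Between CD38-negative and CD38-positive cells, 1 donor stood apart for each of BCL2 (1.11, others -0.89 to -0.52), BCL2A1 (-3.03, others 0.51 to 1.78) and SUCLA2 (-0.078, others -0.49 to -0.42). The same held, in different donors, for mitochondrially encoded genes (1.04, others -0.10 to 0.03) and the anti-apoptotic BCL2 family (-0.56, others 0.13 to 0.34). Among the 9 diagnosis libraries the share of reads from HBB, a haemoglobin gene, reached 0.231% in 1 library and at most 0.0357% in the others. Outside the matched comparison, HBB took 34.5% of reads in 1 of 6 relapse libraries, against at most 0.147% in the others.

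Lower monocyte and granulocyte progenitor markers at relapse were the first pattern weighed. Library scaling, which moves all genes alike, is argued against, since the monocyte list change minus the mean change of the other lists was -1.20 ± 0.65 (SD) log2 units and negative in 6 of 6 donors, a reference chosen after others had been tried. A smaller share of mature monocytes in the relapse sorts stays open. It would leave the primary granule genes MPO, ELANE, PRTN3, AZU1 and CTSG and the progenitor membrane gene MS4A3 unchanged or higher. These 6 changed by -1.26 ± 1.47 (SD), lower in 5 of 6 donors but by less on average than 1 SD over donors. MS4A3 was the only member not lower on average (0.05). All 6 belong to the progenitor list whose fall is part of this pattern, so they do not test it independently. Stage of disease, the difference named by the design, stays open too, and the list counts given further on do not exclude chance.

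Lower cell cycle genes in CD38-negative cells were the second pattern. Library scaling is argued against in the same way, by a cell cycle change minus the mean change of the other lists of -1.80 ± 1.12 (SD, n = 5). Dilution of leukaemic RNA by lymphoid and erythroid cells would lower stem cell genes as much as cell cycle genes. The stem list exceeded the cell cycle list by 2.36 ± 1.25 (SD), in 5 of 5 donors, but the gate itself selects for stem cell genes. In 2 of 5 donors neither the T and NK cell nor the erythroid list was higher. Cell cycle genes changed there by -3.29 and -0.27, the largest and the smallest drop. Dilution therefore stays open. A slower cycle in CD38-negative cells is a candidate explanation that no test here addressed.

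The third pattern was that DESeq2 called 243 genes at relapse where limma and edgeR called 0. Of these, 74.5% (95% interval 68.5% to 79.8%, exact Clopper-Pearson) went the same way in all 6 donors, below the 85.6% among as many limma genes of smallest p. Among all genes tested 5.37% did, and 187 of the 243 were also among those limma genes, which were ranked by a paired test that favours genes going the same way. Whether single donors account for part of the DESeq2 calls therefore stays open. Only 1 of 32 exchanges of stage within donors, the real one, gave as many DESeq2 calls, and the highest other gave 143. That is the lowest share that 32 exchanges can reach. It carries no allowance for the other counts tried with the same exchanges, so chance is not excluded for this count. In simulations of that design DESeq2 made 57 false calls and limma 5.

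The same 32 exchanges were applied to the other counts. For genes past the adjusted threshold at relapse, 32 of 32 gave as many as the real count of 0, the highest other also being 0. For genes at an unadjusted p under 0.05, 3 of 32 gave at least the real 1380, the highest being 1566, so chance is not excluded. For gene lists, 14 of 32 gave at least the real 12 and the highest gave 17, so chance is not excluded for the number of lists past camera. In the CD38 comparison the 16 exchanges are too few for a share under 0.05. The real counts were 0 genes (16 of 16, highest other 0), 4521 genes unadjusted (1 of 16, highest other 3846) and 16 lists (4 of 16, highest other 18). The 4 exchanges of the interaction are also too few, and 4 of 4 gave 0 genes. Other splits, which put both values of some donors on 1 side and so rest on fewer donors, reached 3 genes for relapse and 107 for the CD38 gate. At an unadjusted p under 0.05 they reached 1713 and 4779 genes, more than the real 1380 and 4521. For lists past camera they reached 18 in each comparison.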

How the results depend on the processing

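The pseudocounts 0.5 and 8, the TMM rescaling in limma and the marker covariates were chosen after seeing the data. The edgeR fit with TMM is the test that the design named for raw counts. Its use on recovered reads, with the filter used for limma, was decided after limma had taken its place. For relapse against diagnosis, the count of 0 genes became 243 with DESeq2 (76 higher, 167 lower), which gave no adjusted p for 2890 genes. It became 1 with the 18 matched libraries unsummed and 1 with all 24 unsummed, both with a donor block, and that gene was SLC36A4 both times. Leaving out each donor gave 0 to 1 genes (HK3 without 1 donor, RNASE2 without another). For the CD38 gate, the count of 0 became 2050 with DESeq2 (911 higher, 1139 lower, no adjusted p for 1635 genes) and 4 with limma-voom (S1PR1, COCH, MS4A3 and CYTIP). It became 3677 with the 9 pairs as blocks (1876 higher, 1801 lower), a fit that counts several pairs of a donor as independent. Leaving out each donor gave 0 to 1174 genes, and 1 donor alone accounts for the 1174. With no replicate block, both counts of genes stayed 0, and 9 (relapse) and 14 (CD38) lists passed in place of 12 and 16. The interaction stayed at 0 genes in every fit run. The cause of these differences was not tested, apart from the fewer donors or repeated donors that define some of them.

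Lists past the set test fell from 12 to 0 at relapse and from 16 to 0 for the CD38 gate, both with an estimated correlation and with fry. The mixed form of fry, which asks for changes in any direction, passed 10 and 17 lists. Leaving out each donor gave 11 to 13 and 14 to 17 lists, but not always the main ones. At relapse the call held in 3 of 6 such fits for cell cycle, 4 for p53 targets and stem markers, and 5 for cholesterol synthesis, immediate early and erythroid lists. For the CD38 gate it held in 2 of 5 for B and plasma cell and erythroid markers and in 4 for immediate early genes. The other lists kept theirs. Among lists at relapse past the threshold in the main or the alternative fit, these turned direction. With all 24 libraries summed they were interferon response (adjusted p = 0.0428), cell cycle (0.243), cytosolic ribosomal proteins (1.2e-05) and T and NK cell markers (0.0217). With CD38-positive libraries only it was T and NK cell markers (0.000102), and without 1 donor erythroid markers (0.992, where the other left-out fits kept the direction, the lowest at 0.00307). With the monocyte marker mean as a covariate they were PPAR regulators (0.782), amino acid catabolism (0.0254), pro-apoptotic BCL2 family (0.0238), p53 targets (0.344), NRF2 targets (0.0261), interferon response (3.3e-06), cell cycle (0.121), ribosomal proteins (3.5e-15), LSC17 (0.620), stem and progenitor markers (0.722) and, by construction, monocyte markers (0.449). The cause was not tested. Because the monocyte covariate overlaps with stage, its fits cannot separate stage from monocyte content. No named gene had a sign opposite to the main fit in a fit that called it. Among those not called in the fit at hand, up to 11 of 59 at relapse (monocyte covariate) changed sign. For the CD38 gate up to 4 of 72 did (1 donor left out). With lymphoid and erythroid covariates the CD38 genes at an unadjusted p under 0.05 went from 4521 to 1384. Under TMM and DESeq2 scaling the median of all genes in the CD38 comparison moved from 0.08 to 0.01 log2 units. Depth, at 18.1 to 33.6 M reads, limits the named genes that had a normalised count of 0 in some donors, such as PPARGC1A and HIST3H2A.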

Other observations

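Genes of amino acid transport split in the CD38 comparison, although the list as a whole did not pass (camera adjusted p = 0.182). Over the list alone, SLC38A1 (1.27 ± 0.18 SE), SLC43A2 (1.22 ± 0.39), SLC7A6 (0.37 ± 0.12) and SLC6A6 (0.36 ± 0.10) were higher in CD38-negative cells. SLC7A1 (-0.83 ± 0.19), SLC7A5 (-0.66 ± 0.11) and SLC43A1 (-0.65 ± 0.17) were lower. These genes were chosen after their values were seen. At relapse, the lysosomal amino acid transporters SLC36A4 (-0.72 ± 0.09) and SLC36A1 (-0.63 ± 0.16) fell when adjusted over the same list, again chosen after their values were seen, while the list did not pass (camera adjusted p = 0.834).

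Glycolysis genes did not pass as a list in either comparison (camera adjusted p = 0.329 at relapse and 0.0531 for the CD38 gate). In CD38-negative cells LDHB (-0.73 ± 0.17 SE), TPI1 (-0.48 ± 0.11), PGAM1 (-0.44 ± 0.12) and GPI (-0.40 ± 0.09) fell when adjusted over the list alone, and were likewise chosen after their values were seen.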
